A study of Mus musculus with 24 samples.

How the data were processed

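Gene expression was measured by RNA sequencing of adult mouse liver pieces in 24 libraries, 1 per mouse, in 8 groups of 3. The groups crossed genotype, wild type (WT) or Pcsk9 knockout (KO) on a C57BL/6J background, with 4 conditions: intact females, males, ovariectomized females with a placebo pellet, and ovariectomized females with a pellet of 17-beta-estradiol (E2). Per the labels the ovariectomized mice were 11 weeks old and the intact mice 3 months old, so ovariectomy went together with a different labelled age, surgery and a pellet. The labels state the E2 dose as 1 microgram per day in one place and as about 1 milligram per day in another, and the dose is therefore treated as unknown here. The treatment text mentions sham surgery, but the labels of the intact groups do not say whether those mice had it.

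The deposited table holds normalized signal values for each gene and library, 1 column per library. Per the submitters' processing notes, STAR 2.5, featureCounts 1.5, DESeq2 and genome build GRCm38 were used. The step between values in each column showed them to be whole reads divided by 1 size factor per library: 99.99985% of the values were whole multiples of the step, within a tolerance of 0.01 read. Size factors recomputed by the DESeq2 median-of-ratios method from the recovered reads differed from those steps by at most 0.014%. In 3 libraries (WT females 1 and 3 and KO E2 female 1) the size factor lay within 1% of 1. The table had 54228 genes with values, of which 22380 were at 0 in all libraries. Vldlr and Ldlrad1 carried no values and were not analysed here. Afg3l2 and Gm21762 each had 1 value that was not a whole multiple and equalled the value to its left, and were left out. Of the other genes, 31846 were above 0 in at least 1 library.

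The recovered reads assigned to genes came to between 20.8 M and 31.1 M per library, with a median of 26.6 M. Size factors ran from 0.800 to 1.19, so 1 read was worth about 1 normalized count. Intervals on read counts are exact 95% binomial intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. Normalized counts of 0 to 3 reads in a group carry no usable fold change, and for such genes the levels are given. Fitted fold changes of genes near 0 in one group depend on the pseudocount.

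The choices of test, filter, threshold, gene lists, naming rule and alternative settings were made before the data were examined. Values were taken as log2(value + 1), and genes were kept when at least 3 of the 24 libraries had a value of 10 or more, which left 16411 genes. limma 3.58.1 in R 4.3.3 was fitted to all 24 libraries with 1 mean per group, 16 residual degrees of freedom and a mean-variance trend. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, and a gene was called changed at an adjusted p under 0.05. Standard errors (SE) are those of the moderated fit, and SD is the spread between the 3 libraries of a group. An exact permutation test of 3 libraries against 3 cannot give a two-sided p under 0.1, so none is reported for single genes. There were 12 comparisons: 10 between pairs of groups and 2 interactions, which test whether the genotype effect differed between the sexes and whether the E2 effect differed between genotypes. A pair of averaged comparisons (KO against WT over the 4 conditions, and E2 against placebo over both genotypes) was added after seeing the data.

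A total of 37 gene lists (26 pathway or gene-group lists and 11 lists of cell type markers) was fixed, and the 34 lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera asks whether a list moved against all other genes. The same test with the correlation estimated for each list is given beside each call. The numbers of list members that passed are given over all genes tested and adjusted over the list alone. Adipose, exocrine pancreas and skeletal muscle markers had only 2, 1 and 1 tested members and were not tested. The lists were: cholesterol synthesis; other targets of the sterol-sensing factor SREBP2; LXR targets; the LDL receptor family and its partners; ectodomain sheddases and their inhibitors; proprotein convertases; fatty acid synthesis; PPARA targets and fatty acid oxidation; bile acids; lipoproteins and their enzymes; male-biased and female-biased liver genes; estrogen and growth hormone response; sex-chromosome genes; acute phase; inflammatory cytokines; interferon response; unfolded protein response; xenobiotic and NRF2 response; circadian clock; gluconeogenesis and glucose use; cell cycle; heat shock and immediate early genes; mitochondrial transcripts; pericentral and periportal hepatocytes; and markers of Kupffer cells and macrophages, sinusoidal endothelium, stellate cells and fibroblasts, cholangiocytes, lymphocytes, neutrophils, erythroid cells and mesothelium.

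Genes were picked by rule, and part of them is printed: Pcsk9 and Ldlr in every comparison, and up to 10 genes with the largest rise and up to 10 with the largest fall per pair of groups. These had to be changed, to have a mean of 50 or more in the higher group and to show no overlap between the 3 libraries of one group and the 3 of the other, which chance gives for 10% of genes. Unnamed gene models were left out of the report. Up to 4 members with the smallest p were named from each list with a camera call or at least 2 changed members, and interactions took up to 5 genes in each direction without the overlap condition. Cholesterol synthesis and LDL receptor family genes could be named as values anywhere. Other genes are said to have been chosen after their values were seen.

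Sensitivity on planted changes was tested on simulated data with the observed spread, with 200 genes of a mean of 50 or more changed 1.5-fold, 2-fold or 4-fold. limma recovered 47.8%, 82.1% and 100% of these for KO against WT in intact females, with 6 false calls among 159. The shares were 43.3%, 86.6% and 100% for E2 against placebo in WT (9 false among 162) and 41.8%, 92.5% and 100% in KO (7 false among 163). DESeq2 1.42.0 made 27, 27 and 16 false calls in the same data, and edgeR 4.0.16 made 4, 12 and 7.

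The replicate numbers 1 to 3 were checked as possible pairs by correlating the residuals of equally numbered libraries. KO and WT placebo females correlated at 0.168, 0.157 and 0.267, and KO and WT E2 females at 0.120, 0.170 and 0.108, above the set limit of 0.1 for every number. The other 8 pairs of groups did not pass for every number. For 6 of the 24 libraries the best correlated library of another group had the same number. A fit with the replicate number as a block was therefore compared in the paired comparisons.

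The alternatives were: edgeR quasi-likelihood and DESeq2 on the recovered reads, TMM factors, quantile normalization, pseudocounts of 0.5 and 5, no filter, a mean over all libraries of 50 or more, no trend, a fit of only the groups compared, the replicate block, and leaving out each library in turn. A block in a fit of only the 2 groups compared, and the omission of the 4 libraries with a normalized Saa1 above 5000, were added after seeing the data. Positions are GRCm38 coordinates from GENCODE M21. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.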

Results

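Livers of 24 mice (8 groups of 3) were compared, WT and KO in 4 conditions, with 20.8 M to 31.1 M assigned reads each. Pcsk9 (ENSMUSG00000044254, chromosome 4, 106442329 to 106464329, minus strand) encodes a secreted protein that directs the LDL receptor to degradation, and its reads checked the genotype labels. In the 12 WT libraries Pcsk9 lay between 688.2 and 2796.5 normalized counts, and in 11 KO libraries between 0.0 and 4.1. The remaining KO library, E2 female 1, had 20.8. Reads were summed over 3 libraries, and the shares allow for size factors. KO females had 1 Pcsk9 read against 4972 in WT, or 0.018% (95% exact interval 0.000% to 0.10%), and KO males 3 against 2930, or 0.093% (0.019% to 0.273%). KO placebo females had 9 reads against 4189, or 0.218% (0.10% to 0.414%), and KO E2 females 23 against 6765, or 0.386% (0.245% to 0.580%), of which 21 came from E2 female 1.

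The sex labels were checked with Xist, which silences an X chromosome in females, and with the Y-linked genes Ddx3y, Eif2s3y and Uty. Xist lay between 7924 and 13352 in the 18 female libraries and between 4.4 and 30 in the 6 male libraries. Ddx3y ran from 1.0 to 5.0, Eif2s3y from 0 to 6.0 and Uty from 0 to 10.0 in intact females, and all 3 from 0 to 1.7 in ovariectomized females. The origin of these few Y-linked reads in females was not tested.

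The first question was what loss of Pcsk9 did to the hepatic LDL receptor transcript and to hepatic gene expression in each condition. Ldlr (ENSMUSG00000032193, chromosome 9, 21723483 to 21749919, plus strand) encodes the receptor that takes up LDL. Its mean ± SD (n = 3) was 5260 ± 644 in KO and 4746 ± 749 in WT intact females (log2 fold change 0.15, SE 0.17, adjusted p = 0.926). The means were 3648 ± 391 and 4082 ± 284 in males (-0.17, SE 0.17, adjusted p = 0.683). They were 4439 ± 282 and 4223 ± 1194 in placebo females (0.11, adjusted p = 0.867) and 5546 ± 1001 and 5735 ± 563 in E2 females (-0.06, adjusted p = 0.942). Without WT placebo female 1 the placebo value was -0.14, and without KO E2 female 1 the E2 value was 0.08. The 22 tested genes of the LDL receptor family and its partners, among them Lrp1, Sort1 and Scarb1, had no camera call in any of these 4 comparisons (adjusted p = 0.26, 0.302, 0.944 and 0.256).

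**Figure D1:**
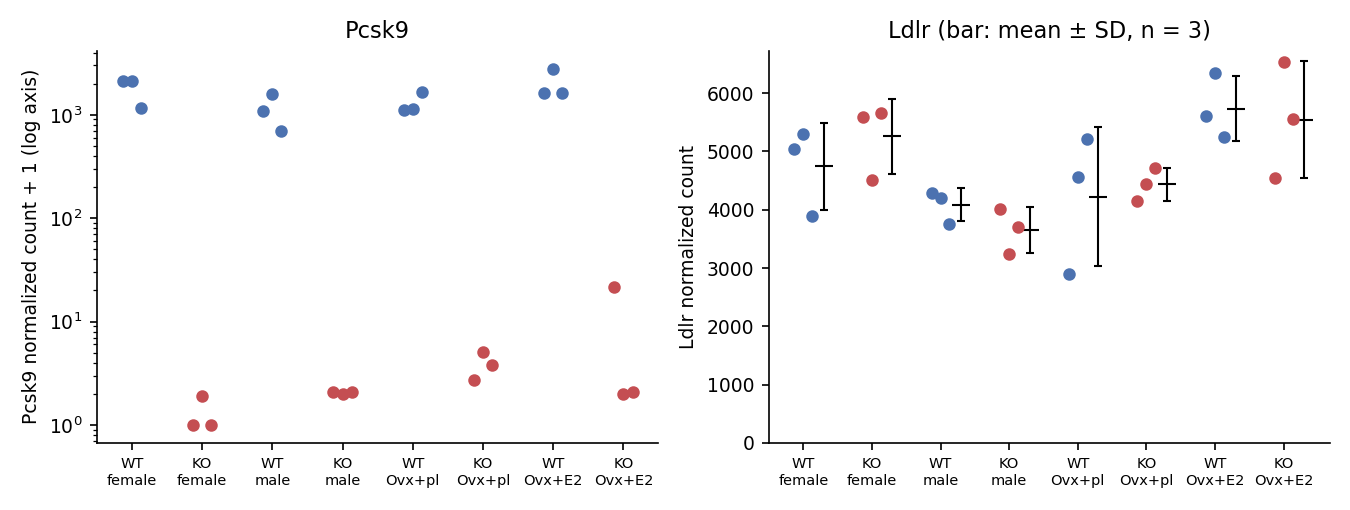
Pcsk9 as normalized count + 1 on a log axis (left) and Ldlr as normalized counts (right) for each library by group, WT blue and KO red. Bars on the right show mean ± SD, n = 3.

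In intact females, KO against WT asked what the knockout changed with ovaries in place. Besides Pcsk9 (adjusted p = 1.04e-09), Dab1 rose from 3.32 ± 3.50 to 52.7 ± 20.3 (log2 fold change 4.00, SE 0.57, adjusted p = 0.0055). Dab1 (ENSMUSG00000028519, chromosome 4, 103619359 to 104744844, plus strand) encodes an adaptor of the LDL receptor family members that bind reelin, and it is a neighbour of Pcsk9 on the chromosome. These were the 2 changed genes, 1 up and 1 down, beside 1142 genes with an unadjusted p under 0.05, 3 by edgeR and 28 by DESeq2. Furin, which encodes a convertase able to cleave PCSK9, was at 2418 ± 230 in KO and 1461 ± 439 in WT (0.77, SE 0.17, adjusted p = 0.206).

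No member of any list passed over all genes in intact females, and 8 lists had a camera call. Of 22 PPARA targets, which include Hadhb (-0.35, adjusted p = 0.515) and Acox1 (-0.29, adjusted p = 0.664) of fatty acid oxidation, 21 had values below 0 and 0 passed adjusted over the list alone (camera adjusted p = 4.40e-05, median -0.24). Of 20 male-biased genes 17 had values below 0, and 3 fell over the list alone (camera adjusted p = 3.63e-06, median -0.68). Of 27 female-biased genes 20 had values above 0, such as Sult2a1 at 5207 ± 1656 against 1726 ± 1583 (adjusted p = 0.631), and 0 passed over the list alone (camera adjusted p = 0.0273). WT female 3 stood apart on these lists, with a female-biased mean of -0.04 against 1.76 and 1.94 in the other WT females, and a cholesterol synthesis mean of -0.37 against 0.77 and 0.50. With an estimated correlation the adjusted p values were 0.738 for PPARA targets, 0.605 for male-biased and 0.738 for female-biased genes.

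The 19 genes of the unfolded protein response had 17 values above 0 with camera adjusted p = 0.00719. The 17 clock genes had 12 above 0 with camera adjusted p = 0.0428. The 7 convertases had 6 above 0 (camera adjusted p = 0.0241) and the 12 endothelial markers 10, with Oit3 at 0.23 (camera adjusted p = 0.048). The 7 erythroid markers all had values below 0, with Alas2 at -0.62 (adjusted p = 0.437, camera adjusted p = 0.0344). Over the list alone, 1 convertase and 1 clock gene rose, 1 erythroid marker fell, and 0 passed in the other lists. Adjusted p = 0.605 for the convertases and 0.738 for each of the others with an estimated correlation. The endothelial call was lost without the filter (adjusted p = 0.0659), with TMM (0.0521), with the block (0.0503) and without the 4 libraries with high Saa1 (0.0554). Cholesterol synthesis had no call (adjusted p = 0.376). The count of changed genes was 4 without WT female 3 and 1 in a fit of only these groups. Where leaving out 1 library moved the mean of a called list by over 1.5 times, the move nearest or past 0 is given, or the only one. It was from 0.66 to 0.03 (female-biased), from -0.83 to -0.52 (male-biased) and from -0.31 to -0.13 (PPARA) without WT female 3, from 0.33 to 0.08 (unfolded protein response) without KO female 3, and from -0.26 to -0.04 (erythroid) without WT female 2.

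In males, KO against WT asked what the knockout changed outside females, and 95 genes changed, 50 up and 45 down. Moxd1 (ENSMUSG00000020000), which encodes a monooxygenase related to dopamine beta-hydroxylase, rose from 3.43 ± 2.16 to 128 ± 58.5 (4.92, SE 0.50, adjusted p = 2.47e-05). Dab1 rose from 6.59 ± 1.80 to 104 ± 14.9 (3.81, SE 0.57, adjusted p = 0.00755). E2f8, a cell cycle repressor linked to polyploidy, rose from 64.4 ± 16.3 to 213 ± 43.5 (1.72, SE 0.38, adjusted p = 0.0442). Pnpla2, the triglyceride lipase of lipid droplets, rose from 539 ± 81.7 to 863 ± 44.9 (0.69, SE 0.14, adjusted p = 0.0308). Slco1a4, a bile acid and steroid transporter, fell from 2312 ± 961 to 725 ± 156 (-1.62, SE 0.33, adjusted p = 0.0325). Pcsk9 had an adjusted p of 1.81e-08.

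Sterol and fatty acid lists had camera calls below 0 in KO males. Elovl5 (ENSMUSG00000032349), which elongates polyunsaturated fatty acids, fell from 23160 ± 4094 to 11660 ± 4097 (-1.04, SE 0.23, adjusted p = 0.0457). It was the 1 of 17 fatty acid synthesis genes to pass, 2 fell over the list alone, and 16 had values below 0, such as Fasn (-0.80, adjusted p = 0.164), with camera adjusted p = 0.00205. Of 20 cholesterol synthesis genes 19 had values below 0, with Sc5d at -0.62 (adjusted p = 0.0854) and Hmgcs1 at -0.98 (adjusted p = 0.196). Of these 0 passed over all genes, 1 fell over the list alone, and camera adjusted p = 0.00221. The 13 other SREBP2 targets had 11 values below 0, Stard4 at -0.47 (adjusted p = 0.156), 0 passed in either way, and camera adjusted p = 0.0136. Adjusted p = 0.907 for each of the 3 lists with an estimated correlation. Without the 4 libraries with high Saa1, which leaves KO male 2 as the only KO male and takes the spread from the other groups, the camera values were 0.0823, 0.214 and 0.0937.

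Of 27 female-biased genes 3 fell in KO males, namely the transporter genes Slc22a26 (-1.76, adjusted p = 0.0104) and Slc22a27 (-1.36, adjusted p = 0.0425) and Rtn4 (-0.67, adjusted p = 0.0189). Over the list alone 8 fell, with camera adjusted p = 0.00205, and the list mean of -0.48 was -0.26 without WT male 1. Aurka, a mitotic kinase, rose from 20.1 ± 2.91 to 48.2 ± 8.28 (1.22, SE 0.21, adjusted p = 0.0109) as the 1 of 18 cell cycle genes to pass, 3 rose over the list alone, and camera adjusted p = 0.00622. The acute phase genes had 18 of 20 values above 0, 0 passed in either way, and Saa1, an inflammation-induced apolipoprotein, was at 13580 ± 13960 against 698 ± 132 (3.71, adjusted p = 0.173; camera adjusted p = 2.37e-04). Adjusted p = 0.907 for each of these lists with an estimated correlation. KO males 1 and 3 had Saa1 at 8371.5 and 29394.1, and the acute phase means of the 3 KO males were 0.18, -0.25 and 0.70 beside cholesterol synthesis means of -0.33, -0.21 and -0.65. Of 7 convertases 3 rose over the list alone, with Mbtps1 at 0.23 (adjusted p = 0.083) and Furin at 0.57 (adjusted p = 0.115), camera adjusted p = 0.00622 (0.125 without the high Saa1 libraries), and adjusted p = 0.755 with an estimated correlation.

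The count in males was 94 by edgeR, 462 by DESeq2 and 2678 by unadjusted p. It was 2, 51 and 19 without KO males 1, 2 and 3, 30, 44 and 27 without WT males 1, 2 and 3, 1 without the high Saa1 libraries, with 1 KO male left, and 5 in a fit of only these groups.

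In ovariectomized females with placebo, KO against WT asked for the knockout effect without ovarian hormones. Pcsk9 was the 1 changed gene, from 1295 ± 304 to 2.87 ± 1.17 (-8.41, SE 0.60, adjusted p = 6.70e-08), beside 1634 genes by unadjusted p, 1 by edgeR and 57 by DESeq2. Dab1 was at 3.21 (adjusted p = 0.0813). Cyp7a1, the first enzyme of bile acid synthesis, was at 3851 ± 432 in KO and 1132 ± 651 in WT (1.91, SE 0.42, adjusted p = 0.242).

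The cell cycle list had 18 of 18 values above 0, with Birc5 at 1.38 (adjusted p = 0.262), and 14 members rose over the list alone (camera adjusted p = 2.26e-13). The unfolded protein response had 17 of 19 below 0, and 7 fell over the list alone, with Hyou1 at -0.93 and Manf at -1.09 (camera adjusted p = 2.11e-06). The 16 heat shock genes had 10 below 0 and 5 fell over the list alone, with Hsph1 at -1.02 and Hsp90aa1 at -0.74 (camera adjusted p = 0.00288). Adjusted p = 0.143, 0.442 and 0.693 with an estimated correlation. Interferon genes had 18 of 19 above 0 (camera adjusted p = 1.23e-04), with Stat1 at 2191 ± 1984 against 951 ± 72.9 (adjusted p = 0.417), and Kupffer markers 12 of 13 (camera adjusted p = 0.00521), with Marco at 1.45 (adjusted p = 0.302). KO placebo female 1 had an interferon mean of 1.42 against 0.14 and 0.09 and a cell cycle mean of 1.42 against 0.41 and 0.62, and Kupffer means were 0.88, 0.60 and 0.04 in KO placebo females 1, 2 and 3. Adjusted p = 0.693 for interferon and 0.825 for Kupffer genes with an estimated correlation.

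All 20 cholesterol synthesis genes had values above 0 in KO placebo females, with Dhcr7 at 0.64 (adjusted p = 0.444; camera adjusted p = 0.0154; adjusted p = 0.942 with an estimated correlation). Of 12 LXR targets, which respond to oxysterols, 9 were above 0, with Abcg8 at 0.34, and 1 rose over the list alone (camera adjusted p = 0.0354). PPARA targets had 20 of 22 below 0, with Acaa1b at -0.56 (camera adjusted p = 5.93e-04), and lipoprotein genes 15 of 20, with Apoa2 at -0.29 (camera adjusted p = 0.0328). Lymphocyte markers had 13 of 14 above 0, with Cd19 at 0.73 (camera adjusted p = 0.00813), and mesothelial markers 5 of 5, with Msln at 1.17 (camera adjusted p = 0.0137), beside WT placebo female 2 with a mesothelial mean of -1.96. Adjusted p = 0.693 for each of these 5 lists with an estimated correlation. The acute phase list had 18 of 20 below 0, with Crp at -0.35 (adjusted p = 0.404; camera adjusted p = 0.0485). This became 0.0501 with the block, 0.0515 with TMM and 0.308 with quantile normalization, which also ended the lipoprotein call (0.847), and adjusted p = 0.97 with an estimated correlation for acute phase. Where not stated, 0 members of these lists passed in either way. The count was 2 without WT placebo female 1 and 4 without WT placebo female 3. Without KO placebo female 1 list means moved from 0.44 to 0.00 (interferon), from 0.90 to 0.60 (cell cycle), from 0.40 to 0.21 (Kupffer), from -0.29 to -0.19 (PPARA) and from -0.07 to -0.02 (lipoproteins), and without it or KO placebo female 2 from 0.40 to 0.26 (lymphocytes). Others moved from -0.20 to 0.14 (acute phase) without WT placebo female 1, from 0.92 to 0.23 (mesothelium) without WT placebo female 2, and from -0.25 to 0.08 (heat shock) and from 0.29 to 0.12 (cholesterol synthesis) without KO placebo female 3.

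In ovariectomized females with E2, KO against WT asked for the knockout effect under estradiol, and 3 genes changed, all down. Pcsk9 fell from 2019 ± 674 to 7.62 ± 11.5 (-8.78, SE 0.60, adjusted p = 2.95e-08). Myo15b (ENSMUSG00000034427), an unconventional myosin, fell from 85.3 ± 44.3 to 15.3 ± 3.97 (-2.25, SE 0.37, adjusted p = 0.0295), and Gng12 (ENSMUSG00000036402), a G protein gamma subunit, fell from 1433 ± 352 to 800 ± 88.2 (-0.81, SE 0.13, adjusted p = 0.0295). Dab1 was at 2.33 (adjusted p = 0.209). By unadjusted p 1558 genes, by edgeR 3 and by DESeq2 61 were counted.

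The cell cycle list had 16 of 18 values below 0, with Cdc20 at 28.1 ± 9.90 against 80.6 ± 18.1 (-1.52, adjusted p = 0.209), and 9 fell over the list alone (camera adjusted p = 1.86e-08). PPARA targets had 20 of 22 above 0, with Angptl4, an inhibitor of lipoprotein lipase, at 4789 ± 924 against 2696 ± 934 (0.88, adjusted p = 0.209), and 1 rose over the list alone (camera adjusted p = 1.86e-08). Pericentral markers had 14 of 14 above 0, with Rgn at 0.37 (adjusted p = 0.276), and 2 rose over the list alone (camera adjusted p = 4.90e-07). Stellate markers had 11 of 13 below 0, with Col3a1 at -0.77 (adjusted p = 0.209), and 4 fell over the list alone (camera adjusted p = 8.95e-05). Cholangiocyte markers had 9 of 9 below 0, with Cftr at -1.87 (adjusted p = 0.276), and 2 fell over the list alone (camera adjusted p = 7.08e-04). In the same order, adjusted p = 0.215, 0.265, 0.244, 0.26 and 0.265 with an estimated correlation.

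Bile acid genes had 16 of 19 above 0, with Cyp7a1 at 9050 ± 2415 against 3199 ± 957 (1.5, adjusted p = 0.259), and 1 rose and 1 fell over the list alone (camera adjusted p = 0.00129; adjusted p = 0.265 with an estimated correlation). Lipoprotein genes had 17 of 20 above 0, with Lipc at 0.40 (camera adjusted p = 7.08e-04), and gluconeogenesis 11 of 13, with Pck1 at 0.44 (camera adjusted p = 7.08e-04). Adjusted p = 0.265 and 0.215 with an estimated correlation. Female-biased genes had 22 of 27 above 0, with Fmo3 at 1.14 (camera adjusted p = 0.00141), and cytokines 8 of 10 below 0, with Ccl2 at -1.90 (camera adjusted p = 0.0054). Adjusted p = 0.572 for both with an estimated correlation, and WT E2 female 2 stood apart with Saa1 at 147442.3. Sheddases had 15 of 20 below 0, with Adam15 at -0.53 (camera adjusted p = 0.00694), and periportal markers 13 of 14 above 0, with Sdhd at 0.28 (camera adjusted p = 0.0262). Adjusted p = 0.215 and 0.64 with an estimated correlation. Mitochondrial transcripts had no call in any KO comparison (adjusted p = 0.963, 0.617, 0.958 and 0.0956). Where not stated, 0 members passed in either way. The count was 5 without KO E2 female 1, 1 without KO E2 female 2 or 3 or WT E2 female 2, 10 without WT E2 female 3, 1 without the high Saa1 libraries, and 0 in a fit of only these groups. That fit with the block also gave 0, with Pcsk9 at an adjusted p of 0.386. Quantile normalization ended the calls of bile acids (0.253), lipoproteins (0.181), gluconeogenesis (0.0713) and periportal markers (0.489), and leaving out the high Saa1 libraries those of female-biased genes (0.123), cytokines (0.542) and periportal markers (0.123). List means moved from -0.67 to -0.06 (cytokines), from 0.40 to 0.22 (PPARA), from 0.23 to 0.06 (bile acids) and from 0.12 to 0.03 (lipoproteins) without WT E2 female 2, from -0.70 to -0.35 (cholangiocytes), from 0.59 to 0.39 (female-biased) and from 0.17 to 0.05 (periportal) without WT E2 female 3, from 0.35 to 0.20 (pericentral) without WT E2 female 1, and from -0.35 to -0.52 (stellate) without KO E2 female 2.

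Averaged over the 4 conditions, a contrast chosen after seeing the data, KO against WT changed 12 genes, 7 up and 5 down, and 4 of them besides Pcsk9 lay within 5 Mb of it. Dab1 rose (3.34, SE 0.29, adjusted p = 1.05e-06), and Acot11, an acyl-CoA thioesterase (ENSMUSG00000034853), rose (1.06, SE 0.17, adjusted p = 0.0159). Tceanc2 (ENSMUSG00000028619) fell (-0.56, SE 0.06, adjusted p = 1.03e-04), and Yipf1 (ENSMUSG00000057375) fell (-0.29, SE 0.05, adjusted p = 0.0261). Of the others, Pnpla2 (0.42), Gpr182 (0.29), Idh3a (0.30), Ecm1 (0.40) and St3gal5 (0.53) rose, and Ormdl1 (-0.29) and Zfp367 (-0.29) fell. The averages cover unlike values by condition, with Ecm1 at 0.84 in intact females and 0.77 in males but -0.01 and 0.00 after ovariectomy, Gpr182 at 0.47 and 0.62 but 0.01 and 0.05, and Ormdl1 at -0.51 and -0.54 but 0.12 with E2. The unadjusted count was 1667, and edgeR gave 10 and DESeq2 92.

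**Figure D2:**
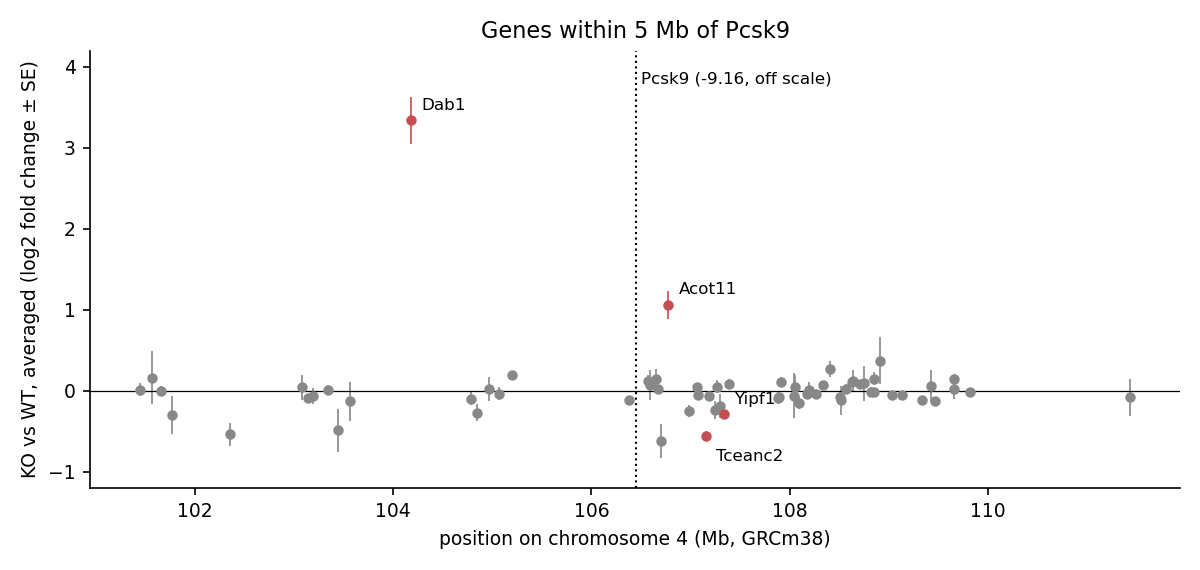
Averaged KO against WT log2 fold change ± SE of tested genes by position on chromosome 4 (Mb, GRCm38), with called genes in red. Dab1, Acot11, Tceanc2 and Yipf1 are labelled, and Pcsk9 at -9.16 lies off the scale.

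The second question was what E2 changed after ovariectomy. In WT, 993 genes changed, 424 up and 569 down, beside 3910 by unadjusted p, 1081 by edgeR and 1522 by DESeq2. Tff3 (ENSMUSG00000024029), a secreted trefoil factor, rose from 9.79 ± 11.5 to 1371 ± 982 (7.20, SE 1.30, adjusted p = 0.00405). Krt4, an epithelial keratin, rose from 2.47 ± 0.578 to 548 ± 446 (6.87, SE 0.97, adjusted p = 0.00124), and Spon1 (ENSMUSG00000038156), a matrix protein, rose from 29.5 ± 0.556 to 591 ± 324 (4.12, SE 0.49, adjusted p = 6.21e-04). Acot1, a thioesterase induced by PPARA, fell from 2275 ± 614 to 338 ± 211 (-2.94, SE 0.48, adjusted p = 0.00212). G0s2, an inhibitor of the lipase encoded by Pnpla2, fell from 5743 ± 999 to 1396 ± 419 (-2.07, SE 0.42, adjusted p = 0.0073). Pcsk9 was at 0.62 (SE 0.60, adjusted p = 0.555) and Ldlr at 0.48 (SE 0.17, adjusted p = 0.0945).

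PPARA targets had the smallest camera p, with 18 of 22 genes fallen, also 18 over the list alone (camera adjusted p = 2.79e-16, median -0.68). Acaa1b, a peroxisomal thiolase, fell from 24630 ± 2476 to 8095 ± 2522 (-1.65, SE 0.23, adjusted p = 0.00124), and Angptl4 (-1.37, adjusted p = 0.002) and Hadha (-0.52, adjusted p = 0.00405) fell. Adjusted p = 0.324 with an estimated correlation. Of 20 lipoprotein genes 3 fell, Lipc (-0.71, adjusted p = 0.00237), Apoa2 (-0.56, adjusted p = 0.0186) and Apoc4 (-0.33, adjusted p = 0.0282), and 5 fell over the list alone (camera adjusted p = 9.52e-05; adjusted p = 0.491 with an estimated correlation).

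Of 20 cholesterol synthesis genes 2 rose, Dhcr7 (0.92, SE 0.27, adjusted p = 0.0478) and Msmo1 (1.16, SE 0.34, adjusted p = 0.0485), and 11 rose over the list alone (camera adjusted p = 9.52e-05, median 0.75; adjusted p = 0.642 with an estimated correlation). Hmgcs1 was at 1.23 (adjusted p = 0.0553) and Hmgcr (ENSMUSG00000021670) at 4747 ± 1689 against 2513 ± 271 (0.87, adjusted p = 0.133). Srebf2, which regulates sterol synthesis, rose from 748 ± 127 to 1283 ± 143 (0.79, SE 0.12, adjusted p = 0.00126) and Cyb5b fell (-0.39, adjusted p = 0.0312), the 2 of 13 other SREBP2 targets to pass (camera adjusted p = 0.126). Among 12 LXR targets 2 rose, the cholesterol exporter gene Abca1 (0.49, SE 0.09, adjusted p = 0.00428) and Cyp7a1 (1.60, SE 0.42, adjusted p = 0.028), and 4 rose over the list alone (camera adjusted p = 0.0696). Of 19 bile acid genes 3 rose, Cyp7a1, Cyp7b1 (2.21, SE 0.33, adjusted p = 0.00146) and Abcc3 (0.66, adjusted p = 0.00591), and 2 fell, with Nr1h4 (-0.33, adjusted p = 0.038), with no call (camera adjusted p = 0.211).

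Acute phase genes had 1 rise, Itih3 (0.91, adjusted p = 0.0285), and 2 over the list alone (camera adjusted p = 0.00557). Neutrophil markers had 8 of 8 values above 0, 0 passed over all genes and 7 rose over the list alone, with S100a9 at 810 ± 982 against 107 ± 57.6 (adjusted p = 0.0585; camera adjusted p = 0.00101). WT E2 female 2 stood apart on both, with an acute phase mean of 2.83 against 0.25 and -0.12 and a neutrophil mean of 4.57 against 1.95 and 1.45. Without this library list means moved from 0.94 to 0.02 (acute phase), from 2.20 to 1.24 (neutrophils), from 0.65 to 0.42 (cholesterol synthesis) and from -0.26 to -0.17 (lipoproteins). Cell cycle genes had 16 of 18 above 0, 0 passed in either way, and Mki67 was at 0.74 (adjusted p = 0.111; camera adjusted p = 0.00557). Stellate markers had 1 rise, Pdgfrb (0.53, adjusted p = 0.0393), and 5 over the list alone (camera adjusted p = 0.00802). Of 9 cholangiocyte markers Spp1 (1.44, SE 0.30, adjusted p = 0.00937) and Sox9 (1.10, adjusted p = 0.0314) rose, also 2 over the list alone (camera adjusted p = 0.0406). Female-biased genes had 2 falls, Acot3 (-2.33, adjusted p = 0.0238) and Cyp2c40 (-1.26, adjusted p = 0.0379), also 2 over the list alone (camera adjusted p = 0.00896). Pericentral markers had 2 falls, Rgn (-0.59, adjusted p = 0.00467) and Slc22a1 (-0.41, adjusted p = 0.0459), and 3 over the list alone (camera adjusted p = 0.0414). Adjusted p = 0.642 for each of these 7 lists with an estimated correlation.

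Among 20 sheddases and inhibitors Bace2, a membrane-bound protease, rose (0.40, SE 0.10, adjusted p = 0.0293), 2 rose over the list alone, and camera adjusted p = 0.0497 (adjusted p = 0.491 with an estimated correlation). The 17 clock genes had 14 values below 0, 0 passed over all genes, and camera adjusted p = 0.0497 (adjusted p = 0.642 with an estimated correlation). Of 16 heat shock genes 4 fell, Hsp90aa1 (-0.96, adjusted p = 0.0106) among them, and the list had no call (adjusted p = 0.818). The count in WT was 290 without WT E2 female 2, 246 and 358 without WT placebo females 1 and 2, 249 without the high Saa1 libraries, and 52 in a fit of only these groups. The cholangiocyte mean moved from 0.62 to 0.26 without WT E2 female 3, and the pericentral mean from -0.18 to -0.03 without WT E2 female 1. Without the high Saa1 libraries calls ended for acute phase (0.841), female-biased genes (0.059), clock genes (0.0951) and sheddases (0.0638), and with quantile normalization for clock genes (0.0883) and pericentral markers (0.316). The sheddase call also ended with a pseudocount of 5 (0.0515), TMM (0.0503) and the block (0.0519).

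In KO, E2 against placebo asked the same without Pcsk9, and 1 gene changed. Knstrn (ENSMUSG00000027331), a spindle protein, fell from 82.0 ± 13.2 to 25.7 ± 6.24 (-1.65, SE 0.21, adjusted p = 0.00204). By unadjusted p 915 genes, by edgeR 25 and by DESeq2 85 were counted. Tff3 was at 466 ± 460 against 4.88 ± 2.46 (5.08, SE 1.30, adjusted p = 0.229), Ldlr at 0.31 (SE 0.17, adjusted p = 0.933) and Srebf2 at 0.48 (adjusted p = 0.171). KO E2 female 3 had Tff3 at 13.7 and Krt4 at 5.3, against 451.7 and 933.1 and against 179.7 and 53.6 in the other KO E2 females.

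The cell cycle list had 17 of 18 values below 0 in KO, 0 passed over all genes and 14 fell over the list alone, with Ccnb1 at -2.14, Cdc20 at -1.85 and Aurka at -1.15 (adjusted p = 0.0515 for all 3). Camera adjusted p = 7.27e-24, and 0.0134 with an estimated correlation, so this call held. KO placebo female 1 stood apart on it, and without this library the list mean was -0.79 in place of -1.09. PPARA targets had 19 of 22 below 0, with Plin2 at -0.57 (adjusted p = 0.47; camera adjusted p = 4.57e-04), and fatty acid synthesis 14 of 17, with Elovl6 at -0.76 (camera adjusted p = 0.0351). Adjusted p = 0.651 and 0.782 with an estimated correlation. Acute phase genes had 19 of 20 above 0 and 1 rose over the list alone, with Itih3 at 0.82 (adjusted p = 0.407; camera adjusted p = 3.34e-07), and neutrophil markers 8 of 8 above 0, with S100a9 at 2.06, and 6 rose over the list alone (camera adjusted p = 3.34e-07). Adjusted p = 0.549 and 0.501 with an estimated correlation, beside Saa1 at 36426.3 in KO E2 female 3 and neutrophil means of 0.39, 3.50 and 3.02. Estrogen and growth hormone response genes had 12 of 14 above 0 and 1 rose over the list alone (camera adjusted p = 0.00935; adjusted p = 0.513 with an estimated correlation). WT had no call (library means 0.30 to 0.75 with E2, -0.45 to 0.24 with placebo).

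Interferon genes had 15 of 19 values below 0, with Bst2 at -0.51 (camera adjusted p = 0.00502), lymphocyte markers 11 of 14, with Nkg7 at -0.76 (camera adjusted p = 0.0314), erythroid markers 7 of 7, with Hbb-bs at -0.67 and 2 fallen over the list alone (camera adjusted p = 1.76e-04), and mesothelial markers 5 of 5, with Msln at -1.02 (camera adjusted p = 0.0157). Adjusted p = 0.782, 0.743, 0.501 and 0.549 with an estimated correlation. The unfolded protein response had 16 of 19 above 0, with Herpud1 at 0.34 (camera adjusted p = 0.00553), gluconeogenesis 10 of 13, with Tat at 0.68 (camera adjusted p = 0.0258), and heat shock genes 10 of 16, with Fos at 2.14 (camera adjusted p = 0.0466). Adjusted p = 0.57, 0.549 and 0.782 with an estimated correlation. Cholesterol synthesis (adjusted p = 0.0855) and the LDL receptor family (adjusted p = 0.941) had no call. The count in KO was 2 without KO E2 female 1, 21 without KO E2 female 3, 29 without KO placebo female 2, 23 without the high Saa1 libraries, and 0 in a fit of only these groups. Calls ended without the high Saa1 libraries for fatty acid synthesis (0.23), the unfolded protein response (0.0847) and gluconeogenesis (0.0576), with quantile normalization for gluconeogenesis (0.177), heat shock (0.0859) and lymphocytes (0.0655), and for heat shock without the filter (0.0644) and with TMM (0.0538). Interferon genes moved from a list mean of -0.28 to 0.16 without KO placebo female 1, lymphocyte markers from -0.30 to -0.16 without it or KO placebo female 2, PPARA targets from -0.29 to -0.14 without KO placebo female 2, and heat shock genes from 0.53 to 0.20 without KO placebo female 3. Without E2 libraries means moved from -0.27 to -0.18 (fatty acid synthesis) and from 1.90 to 2.86 (neutrophils) for KO E2 female 1, from -0.88 to -0.48 (mesothelium) and from 0.20 to 0.13 (gluconeogenesis) for KO E2 female 2, and from 0.83 to 0.47 (acute phase) and from -0.46 to -0.28 (erythroid) for KO E2 female 3.

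**Figure D3:**
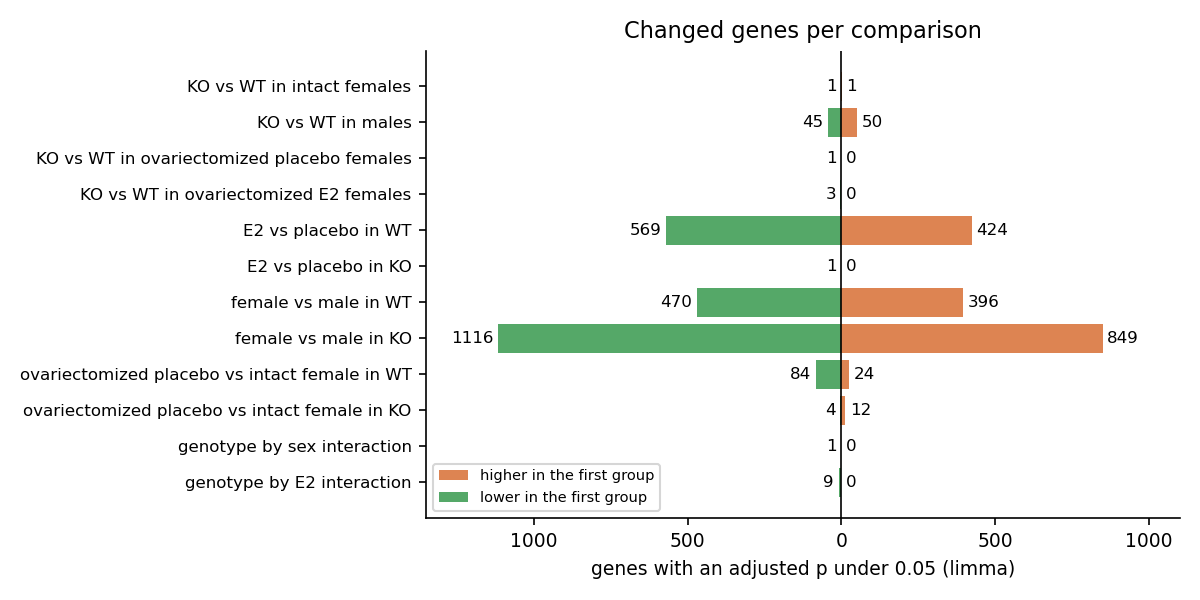
Number of genes with an adjusted p under 0.05 in each of the 12 comparisons, higher in orange and lower in green.

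The E2 fold changes of WT and KO correlated across all tested genes at r = 0.350 (rank correlation 0.236), genes not being independent replicates. Of the 993 genes changed in WT, 831 (83.7%) had the same sign in KO, with a slope of 0.367. Averaged over both genotypes, a contrast chosen after seeing the data, E2 changed 544 genes, 250 up and 294 down (3269 by unadjusted p, 631 by edgeR, 1026 by DESeq2). The interaction of genotype and E2 asked whether the E2 effect differed, and 9 genes passed, all with a lower E2 fold change in KO. They were Knstrn (-2.26, SE 0.30, adjusted p = 0.00351), Cdc20 (-2.71, SE 0.49, adjusted p = 0.0387), Spag5 (-2.62, SE 0.44, adjusted p = 0.0325), Knl1 (-2.52, SE 0.45, adjusted p = 0.0387), Tpx2 (-2.27, SE 0.39, adjusted p = 0.0325), Aurka (-1.57, adjusted p = 0.0442) and, named after their values were seen, Ttk (-2.96), Kif14 (-2.72) and Kif20a (-2.13). By unadjusted p 1627 genes, by edgeR 22 and by DESeq2 84 were counted. Ldlr was at -0.17 (SE 0.24, adjusted p = 0.846).

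**Figure D4:**
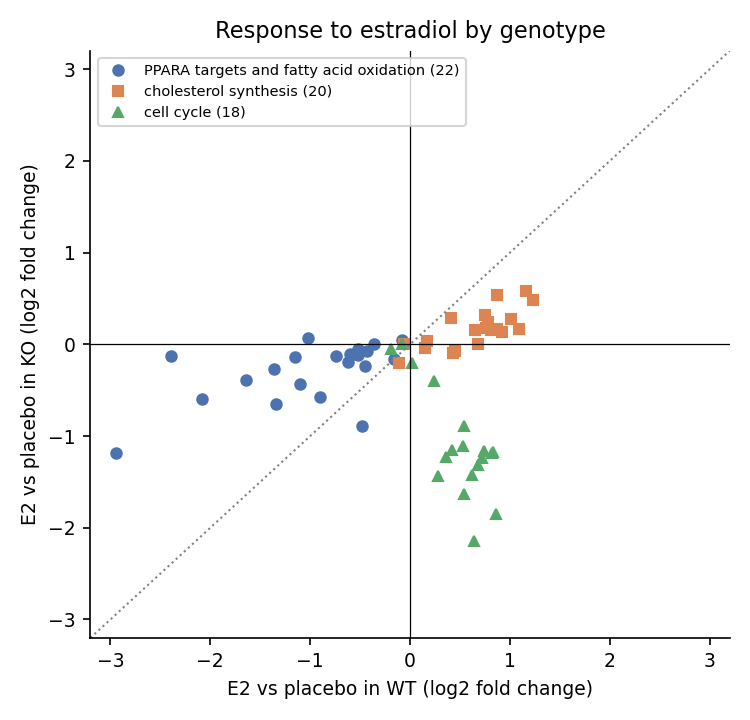
Log2 fold change of E2 against placebo in WT (horizontal) and KO (vertical) for 22 PPARA targets, 20 cholesterol synthesis genes and 18 cell cycle genes. The dotted line marks equal values.

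In this interaction 2 of 18 cell cycle genes had a lower E2 fold change in KO, and 14 over the list alone (camera adjusted p = 4.27e-18), and adjusted p = 0.045 with an estimated correlation. PPARA targets had 21 of 22 values above 0, with Acaa1b at 1.26 (adjusted p = 0.206) and Angptl4 at 1.10 (adjusted p = 0.256), and 8 rose over the list alone (camera adjusted p = 5.44e-11; adjusted p = 0.4 with an estimated correlation). Cholesterol synthesis had 19 of 20 below 0, with Dhcr7 at -0.78 (camera adjusted p = 0.00432; adjusted p = 0.565 with an estimated correlation). Further calls were for lipoproteins (1.48e-04), stellate markers (0.00217), pericentral markers (0.00217), lymphocytes (0.00217), interferon (0.00478), mesothelium (0.00478), cholangiocytes (0.0143), gluconeogenesis (0.0169), Kupffer cells (0.0178), the unfolded protein response (0.0222), erythroid markers (0.0367), bile acids (0.0398), sheddases (0.0422) and female-biased genes (0.0462). With an estimated correlation, adjusted p lay between 0.4 and 0.565 for each of these 14 lists. Over the list alone, 2 lipoprotein genes, 3 stellate markers, with Col3a1 at -1.29 (adjusted p = 0.0844), and 2 cholangiocyte markers, with Spp1 at -1.43, passed. The count was 35 without KO placebo female 2, 19 without WT E2 female 3, 20 without WT placebo female 2, 6 without KO E2 female 1 and 1 without each other library, and 0 without the high Saa1 libraries or in a fit of only these groups. Quantile normalization ended the calls of lipoproteins (0.283), pericentral markers (0.139), bile acids (0.932), the unfolded protein response (0.254), gluconeogenesis (0.46) and female-biased genes (0.283). Leaving out the high Saa1 libraries ended those of cholesterol synthesis (0.316), bile acids (0.181), female-biased genes (0.287, and 0.055 with a pseudocount of 0.5), Kupffer cells (0.517) and erythroid markers (0.23). List means moved from -0.48 to -0.25 (cholesterol synthesis), from -0.45 to -0.07 (Kupffer), from 0.20 to 0.11 (lipoproteins) and from 0.09 to -0.08 (bile acids) without WT E2 female 2, from -0.82 to -0.46 (cholangiocytes), from 0.44 to 0.24 (female-biased) and from 0.15 to 0.00 (unfolded protein response) without WT E2 female 3, and from -1.45 to -0.76 (mesothelium) and from 0.24 to 0.15 (gluconeogenesis) without WT placebo female 2. The pericentral mean moved from 0.28 to 0.13 without WT E2 female 1, and interferon from -0.43 to 0.00 without KO placebo female 1.

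**Figure D5:**
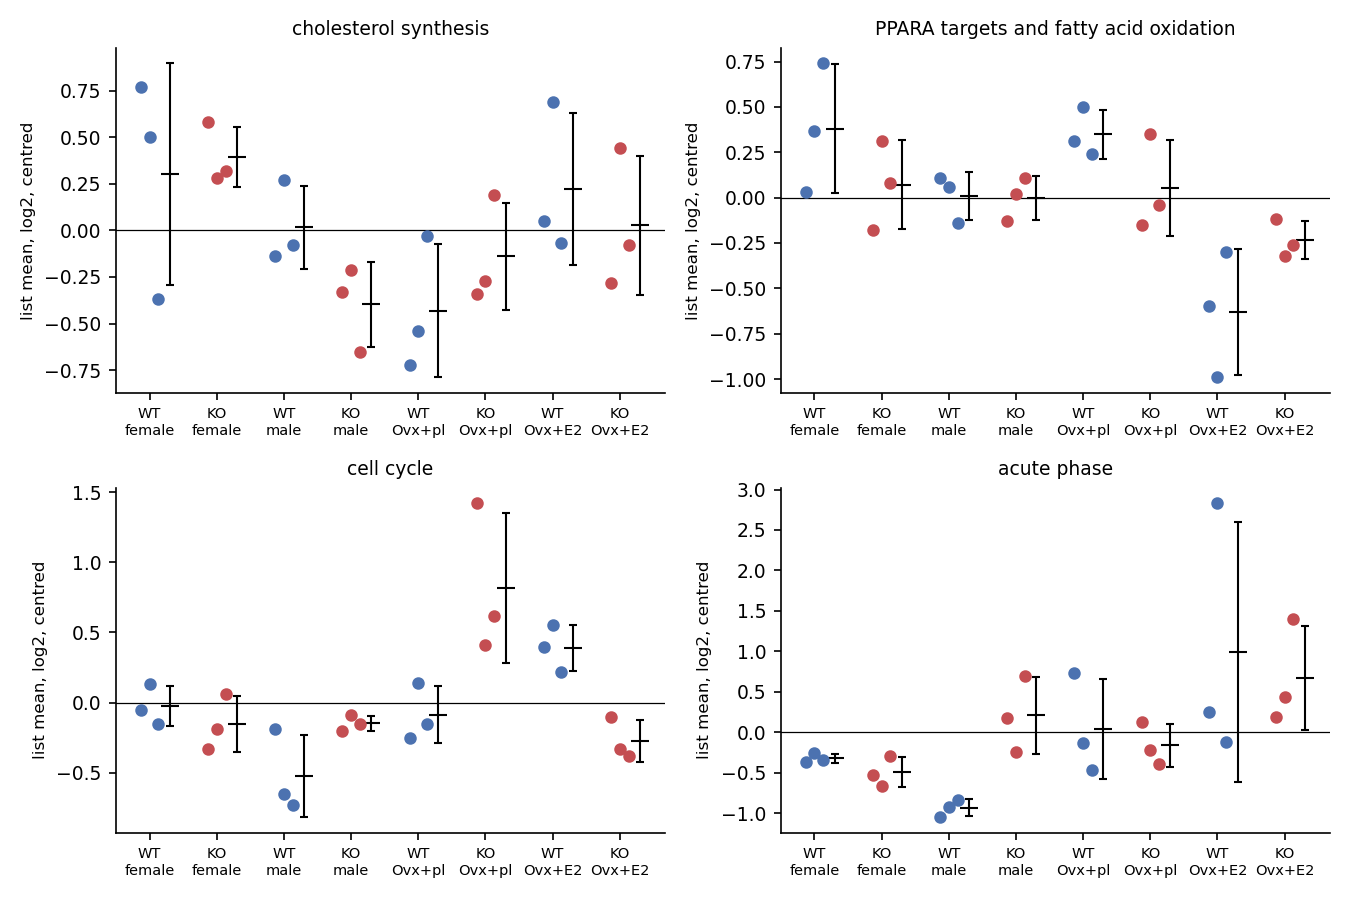
Mean centred log2 value of the cholesterol synthesis, PPARA target, cell cycle and acute phase lists in each library by group. Points are libraries and bars are mean ± SD, n = 3.

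The third question was how the sexes differed in each genotype. In WT, 866 genes differed, 396 higher and 470 lower in females (3346 by unadjusted p, 801 by edgeR, 1090 by DESeq2). Cyp2b9, a female-specific steroid hydroxylase, was at 9810 ± 2610 in females and 4.73 ± 3.25 in males (10.86, SE 0.34, adjusted p = 6.77e-15), and Fmo3, which oxidizes trimethylamine, at 9138 ± 4334 and 4.70 ± 3.23 (10.64, SE 0.44, adjusted p = 3.68e-13). Cyp4a12a, a male-specific fatty acid hydroxylase, was at 33.4 ± 22.6 and 5073 ± 1918 (-7.34, SE 0.69, adjusted p = 2.65e-07), and Mup20, a male pheromone protein, at 2141 ± 902 and 169700 ± 23060 (-6.41, SE 0.65, adjusted p = 8.76e-07). In KO, 1965 genes differed, 849 higher and 1116 lower (4523 by unadjusted p, 1935 by edgeR, 2156 by DESeq2). Cyp2b9 was at 11690 ± 585 and 4.88 ± 2.32 (11.05, SE 0.34, adjusted p = 2.36e-15) and Cyp4a12a at 5.69 ± 4.30 and 5939 ± 562 (-10.10, SE 0.69, adjusted p = 1.05e-09). Pcsk9 in WT was at 0.71 (SE 0.60, adjusted p = 0.546).

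The female-biased list had 26 of 27 genes risen in WT and 27 of 27 in KO (camera adjusted p = 1.09e-62 and 1.34e-56), among them the transporter gene Slc22a26 (7.54 and 9.53). The male-biased list had 16 of 20 fallen in each (camera adjusted p = 7.67e-27 and 6.97e-27), and in KO 17 fell over the list alone. Elovl3 (-6.23 and -6.46) and C6 (-3.10 and -4.20) were among them. With an estimated correlation both lists held, with adjusted p = 2.02e-04 and 3.72e-04 for female-biased and 0.00123 and 0.00122 for male-biased genes. The sex-chromosome list had 5 rises and 4 falls in WT and 4 and 4 in KO, and in WT its median was 0.38 and its mean -2.69 (camera adjusted p = 0.192). The sex differences of WT and KO correlated at r = 0.774 (rank correlation 0.512), with 833 of the 866 WT genes (96.2%) having the same sign in KO.

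Cholesterol synthesis in KO had 8 of 20 genes higher in females, and 15 over the list alone (camera adjusted p = 1.22e-06, median 0.69; adjusted p = 0.7 with an estimated correlation). Hmgcr was at 5979 ± 420 in females and 2490 ± 244 in males (1.27, SE 0.35, adjusted p = 0.0206) and Hmgcs1 at 14920 ± 3657 and 5661 ± 1642 (1.41, SE 0.37, adjusted p = 0.0169). In WT 1 gene of the list passed, Dhcr24, which encodes the last reductase of the pathway (0.65, SE 0.15, adjusted p = 0.0136), also 1 over the list alone (camera adjusted p = 0.0453; adjusted p = 0.844 with an estimated correlation). Of 13 other SREBP2 targets in KO 7 were higher and 9 over the list alone, with Srebf2 at 0.69 (SE 0.12, adjusted p = 3.20e-04) and Insig1 at 0.90 (adjusted p = 0.00813; camera adjusted p = 4.81e-04). Of 17 fatty acid synthesis genes in KO 6 were higher and 8 over the list alone, with Fasn at 41390 ± 12650 and 12600 ± 2480 (1.69, SE 0.28, adjusted p = 3.07e-04) and Pnpla3 at 381 ± 185 and 25.6 ± 16.0 (3.91, adjusted p = 5.54e-05; camera adjusted p = 2.18e-05). Adjusted p = 0.519 for both with an estimated correlation. Ldlr was higher in KO females (0.53, SE 0.17, adjusted p = 0.0495) and at 0.21 in WT (SE 0.17, adjusted p = 0.535). In KO the LDL receptor family had no call (camera adjusted p = 0.39).

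Lists of other cells had camera calls as well. Endothelial markers had 4 of 12 higher in WT females, 7 over the list alone, with Kdr (0.32, adjusted p = 0.0143; camera adjusted p = 3.49e-04), and 3 in KO, with Stab2 (0.33, adjusted p = 0.0161; camera adjusted p = 0.00545). Adjusted p = 0.154 and 0.484 with an estimated correlation. Lymphocyte markers were above 0 in 14 of 14 in both, with 0 passed in WT (camera adjusted p = 8.06e-04) and 4 higher in KO, 8 over the list alone, with Cd79b at 1.16 (adjusted p = 0.00841; camera adjusted p = 1.67e-04). Adjusted p = 0.588 and 0.519 with an estimated correlation. In WT, 4 of 14 pericentral markers were higher and 6 over the list alone, with the Wnt targets Axin2 (1.18, adjusted p = 0.00609) and Lgr5 (1.19, adjusted p = 0.0315; camera adjusted p = 5.05e-05; adjusted p = 0.521 with an estimated correlation). Of 18 cell cycle genes in WT 2 were higher, Ccnd1 (2.08, adjusted p = 1.25e-04) and Mki67 (1.05, adjusted p = 0.0307), and 3 over the list alone (camera adjusted p = 0.00154). Of 19 genes of the unfolded protein response in WT Asns was lower (-2.76, adjusted p = 0.018; camera adjusted p = 0.0105). Adjusted p = 0.676 for both with an estimated correlation. In WT, interferon genes (17 of 19 above 0, camera adjusted p = 0.0124) and Kupffer markers (13 of 13, camera adjusted p = 0.0105) had 0 passed, and adjusted p = 0.818 with an estimated correlation for both. In KO, the heme enzyme gene Alas2 was lower in females (-3.11, SE 0.18, adjusted p = 1.08e-10) as the 1 of 7 erythroid markers to pass (camera adjusted p = 0.0208; adjusted p = 0.7 with an estimated correlation).

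In lists without a call in KO the LXR targets Abcg5 (0.84) and Srebf1 (1.15) and the acute phase genes Saa1 (-4.29, adjusted p = 0.0407) and Saa4 (-1.32) differed, beside the high Saa1 of KO males 1 and 3. The WT count was 355 and 566 without WT females 2 and 3, 458 and 439 without WT males 2 and 3, and 285 in a fit of only these groups, and list means moved from 0.28 to 0.05 (cholesterol synthesis) without WT female 1 and from 0.37 to 0.19 (interferon) without WT male 1. The KO count was 1069 and 1254 without KO females 1 and 2, 1219 without KO male 1, and 536 without the high Saa1 libraries, with 1 KO male left.

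The interaction of genotype and sex asked whether the knockout effect differed between the sexes. Moxd1 was the 1 gene to pass (-5.64, SE 0.71, adjusted p = 0.00161), with 0 and 0.748 ± 0.660 in KO and WT females, so its size depends on the pseudocount. By unadjusted p 1271 genes, by edgeR 0 and by DESeq2 30 were counted. Ldlr was at 0.32 (SE 0.24, adjusted p = 0.808). Calls above 0 were for fatty acid synthesis (8.35e-06), female-biased genes (1.60e-06), cholesterol synthesis (3.90e-04), other SREBP2 targets (3.90e-04), stellate markers (0.0172), heat shock (0.0394) and cholangiocytes (0.0394). Calls below 0 were for male-biased genes (1.60e-06), acute phase (5.29e-05), cell cycle (3.90e-04), PPARA targets (0.0018) and erythroid markers (0.0417). With an estimated correlation, adjusted p lay between 0.698 and 0.765 for each. Over the list alone, 3 fatty acid synthesis genes, 4 female-biased genes, 1 cholesterol synthesis gene, 4 male-biased genes and 4 cell cycle genes passed. Fold changes of KO against WT in females and males correlated at r = 0.025 without Pcsk9 (rank correlation 0.115). The count was 12 without WT female 1, 2 without KO female 2 or WT male 2, 3 without KO male 3 or WT male 3, 0 without the high Saa1 libraries (1 KO male left), and 4 in a fit of only these groups. The cholesterol synthesis call ended without the high Saa1 libraries (0.0635), that of cholangiocytes without the filter (0.066) and with quantile normalization (0.0506), and that of erythroid markers with the latter (0.0501). Without WT female 3 list means moved from 0.51 to 0.17 (cholesterol synthesis), from 0.72 to 0.44 (other SREBP2 targets), from 1.14 to 0.51 (female-biased) and from -0.30 to -0.11 (PPARA), without WT female 2 from 0.55 to 0.35 (cholangiocytes) and from -0.46 to -0.23 (erythroid), without WT male 1 from 0.30 to 0.17 (stellate), and without KO male 1 from 0.57 to 0.33 (heat shock).

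The fourth question was what ovariectomy with placebo went with, compared with intact females that also differed in surgery, pellet and labelled age. In WT, 108 genes changed, 24 up and 84 down (2620 by unadjusted p, 132 by edgeR, 489 by DESeq2). Cyp7a1 fell from 4206 ± 1989 to 1132 ± 651 (-1.91, SE 0.42, adjusted p = 0.0462), and Idi1, an isomerase of sterol synthesis, fell from 1045 ± 348 to 348 ± 99 (-1.56, SE 0.28, adjusted p = 0.0226). Serpina6, which encodes the corticosteroid-binding globulin, rose from 4481 ± 493 to 8720 ± 1133 (0.96, SE 0.21, adjusted p = 0.0462). Ldlr was at -0.20 (SE 0.17, adjusted p = 0.62) and Pcsk9 at -0.44 (adjusted p = 0.771).

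Of 20 cholesterol synthesis genes in WT all had values below 0, 1 fell, and 8 fell over the list alone, with Hmgcr at -1.15 (adjusted p = 0.109; camera adjusted p = 8.34e-09; adjusted p = 0.631 with an estimated correlation). Of 13 other SREBP2 targets Tmem41b fell (-0.47, adjusted p = 0.0398), also 1 over the list alone (camera adjusted p = 0.00662; adjusted p = 0.641 with an estimated correlation). Of 19 bile acid genes Cyp7a1 and Slco1b2 (-0.53, adjusted p = 0.0462) fell, and 3 over the list alone (camera adjusted p = 0.00359). Of 20 male-biased genes Cyp4a12a fell (-3.15, adjusted p = 0.0462), and 7 over the list alone (camera adjusted p = 0.00158). Of the sex-chromosome genes 2 passed at levels near 0, Eif2s3y at 0 against 4.24 ± 1.57 and Ddx3y at 0.303 against 3.74 ± 2.16 (camera adjusted p = 0.00662). Among 7 convertases 5 rose and 1 fell over the list alone, with Furin at 0.50 (adjusted p = 0.161) and Mbtps2 at -0.52 (adjusted p = 0.0825; camera adjusted p = 0.0273). The unfolded protein response had 14 of 19 above 0 and 4 risen over the list alone, with Hyou1 at 1.11 (adjusted p = 0.0625; camera adjusted p = 0.00318). Adjusted p = 0.631 for each of these 5 lists with an estimated correlation. Neutrophil markers (8 of 8 above 0, Ltf at 3.28, 2 risen over the list alone, camera adjusted p = 0.00411), Kupffer markers (12 of 13, 0.00662), interferon genes (18 of 19, 0.0119) and female-biased genes (18 of 27, 0.0352) lay higher, and pericentral markers (13 of 14 below 0, Lgr5 at -1.13, 1 fallen over the list alone, 0.00662) lower. Adjusted p = 0.641 for each with an estimated correlation. The count in WT was 10, 12 and 22 without WT placebo females 1, 2 and 3, 11, 9 and 210 without WT females 1, 2 and 3, and 2 in a fit of only these groups. The female-biased call ended without the high Saa1 libraries (0.0568), and its mean moved from 0.69 to 0.06 without WT female 3. Other means moved from -0.26 to -0.01 (other SREBP2 targets) and from 0.19 to 0.12 (convertases) without WT female 1, from 0.33 to 0.20 (Kupffer) without WT placebo female 1, and from -0.26 to -0.16 (pericentral) without WT placebo female 3.

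In KO, 16 genes changed with ovariectomy, 12 up and 4 down (2114 by unadjusted p, 33 by edgeR, 315 by DESeq2). Knstrn rose from 25.2 ± 3.11 to 82.0 ± 13.2 (1.66, SE 0.21, adjusted p = 0.00191), Kif20a, a mitotic kinesin, from 48.2 ± 7.42 to 152 ± 47.8 (1.60, SE 0.27, adjusted p = 0.0242), and Aurka from 25.2 ± 2.21 to 64.7 ± 12.9 (1.31, SE 0.21, adjusted p = 0.0211). Creb3l2, a factor of the unfolded protein response, fell from 738 ± 136 to 421 ± 42.7 (-0.80, SE 0.13, adjusted p = 0.0242). Ldlr was at -0.24 (adjusted p = 0.592).

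Of 18 cell cycle genes in KO 1 rose and 14 over the list alone (camera adjusted p = 3.66e-13; adjusted p = 0.151 with an estimated correlation). Cholesterol synthesis had 20 of 20 below 0 and 3 fell over the list alone, with Hmgcr at -1.16 (adjusted p = 0.165; camera adjusted p = 5.66e-07), and neutrophil markers 8 of 8 above 0 (camera adjusted p = 4.76e-04). Adjusted p = 0.46 for both with an estimated correlation. Interferon genes were above 0 in 19 of 19, with Ifit3 at 1.05, and 12 rose over the list alone (camera adjusted p = 6.18e-10), beside KO placebo female 1, and Kupffer markers in 13 of 13, with C1qc at 0.89, and 11 rose over the list alone (camera adjusted p = 2.16e-09). Other SREBP2 targets had 11 of 13 below 0, with Srebf2 at -0.50 (adjusted p = 0.0891), and 1 rose and 5 fell over the list alone (camera adjusted p = 2.98e-04). The unfolded protein response had 17 of 19 below 0 (camera adjusted p = 4.76e-04) and gluconeogenesis 11 of 13, with G6pc at -0.77 (camera adjusted p = 0.0197). Adjusted p = 0.391 for each of these 5 lists with an estimated correlation. Erythroid markers had 7 of 7 above 0, with Hba-a2 at 1.00 (adjusted p = 0.0552), and 6 rose over the list alone (camera adjusted p = 1.28e-07; adjusted p = 0.176 with an estimated correlation). Heat shock genes had 14 of 16 below 0 (camera adjusted p = 4.76e-04), lymphocyte markers 13 of 14 above 0 (camera adjusted p = 0.039), and sex-chromosome genes 8 of 9 below 0, with 2 past the threshold over the list alone (camera adjusted p = 0.00221). Adjusted p = 0.396, 0.63 and 0.197 with an estimated correlation. The count in KO was 1 without KO placebo female 1, 57 without KO placebo female 3, 8, 1 and 9 without KO females 1, 2 and 3, 1 without the high Saa1 libraries, and 2 in a fit of only these groups. Quantile normalization ended the calls of gluconeogenesis (0.156) and lymphocytes (0.0627). Interferon genes moved from a list mean of 0.70 to 0.27 without KO placebo female 1, lymphocytes from 0.34 to 0.20 without it or KO placebo female 2, heat shock from -0.75 to -0.42 without KO placebo female 3, and the unfolded protein response from -0.38 to -0.13 without KO female 3.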

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

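The test of called genes near Pcsk9 and the cell cycle difference without KO placebo female 1 were chosen only after the results were seen. Groups of 3 were not tested for a library far from the others. In the 10 comparisons of 2 groups, 1 of the 10 splits of the 6 libraries, the real one, reached the count, which is too few splits for a share under 0.05. The real counts and the highest other counts were 2 and 0, 95 and 2, 1 and 0, and 3 and 2 for KO against WT in intact females, males, placebo and E2 females. They were 993 and 4 for E2 in WT, 1 and 0 in KO, 866 and 31 for sex in WT, 1965 and 0 in KO, 108 and 2 for ovariectomy in WT, and 16 and 0 in KO. In placebo and in E2 females equally numbered KO and WT libraries passed the correlation limit. In the 4 splits that part every such pair, the highest other count of KO against WT was 0 and 0.

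Both interactions were singled out because a group difference passed its own test. Genotype by sex had 1 changed gene, Moxd1 at -5.64, reached in 17 of 100 groupings of the 12 libraries (highest count 2990). Genotype by E2 had 9, reached in 3 of 100 (highest 447). Groupings also mixed the sexes or pellets, so they cannot test for chance.

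E2 against placebo called 993 genes in WT and 1 in KO. Without WT E2 female 2 (highest Saa1), WT fold changes kept a median ratio of 0.92 (quartiles 0.83 and 1.01) to those with it, which argues against that library as their source. The WT count was 290 without it and 246 without WT placebo female 1, so how far the calls rest on it stays open. For genes picked in 2 WT replicates, the ratio of KO to left-out WT fold changes was 0.33, 0.33 and 0.52 (median 0.33), which argues against an equal response missed by the threshold, although 83.0% to 83.6% had the same sign in KO. Without KO E2 female 3, picked after its Tff3 of 13.7 was seen, the ratios were 0.40, 0.42 and 0.67 (median 0.42), which leaves its part open, and a smaller E2 response in KO livers may remain.

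Genes near Pcsk9 changed in KO. Of 65 other tested genes within 5 Mb, 4 were called in the averaged contrast, against 7 of 16334 elsewhere (one-sided Fisher p = 7.26e-08). That test recounts the calls that prompted it. With called genes set aside, the neighbours had a mean absolute t of 1.24, above 97.9% of 1504 runs of neighbouring genes, which argues against a response to PCSK9 loss independent of position as the whole cause. A local effect of the targeted locus, or strain DNA carried along with it, is a candidate explanation, and the 2 were not told apart. The labels give more than 12 backcrosses, and how much strain DNA remained near Pcsk9 was not tested.

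Cell cycle genes were lower with E2 in KO and not in WT, with Cdc20 at -2.71, Spag5 at -2.62, Knl1 at -2.52, Tpx2 at -2.27, Knstrn at -2.26 and Aurka at -1.57 in the interaction, and a list mean of -1.56. Without KO placebo female 1 it was -1.26, a ratio of 0.81, but the WT part is fixed, so that library's role stays open. The list mean of KO placebo females, 0.82 ± 0.53, lay at least 2.04 standard errors above every other group, the nearest being WT E2 females at 0.39 ± 0.16, but 0.75 standard errors above without KO placebo female 1. The list mean changed with E2 by -1.09 in KO and by 0.48 in WT (SE 0.21 each), so a high level in the KO placebo group does not cover the WT part. Whether that level may account for the KO part, and whether it reflects genotype or these 3 animals, stays open.

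The other list means of genotype by sex with a camera call were 0.51 for cholesterol synthesis, 0.72 for other SREBP2 targets, 0.75 for fatty acid synthesis, 1.14 for female-biased genes, 0.57 for heat shock, 0.30 for stellate and 0.55 for cholangiocyte markers. Below 0 were PPARA targets (-0.30), male-biased genes (-1.08), acute phase (-1.31), cell cycle (-0.51) and erythroid markers (-0.46). For genotype by E2 they were -0.48 for cholesterol synthesis, -0.29 for sheddases, 0.69 for PPARA targets, 0.09 for bile acids, 0.20 for lipoproteins, 0.44 for female-biased genes, -0.43 for interferon, 0.15 for the unfolded protein response and 0.24 for gluconeogenesis. Cell type markers were at 0.28 for pericentral hepatocytes, -0.45 for Kupffer, -0.49 for stellate, -0.82 for cholangiocyte, -0.64 for lymphocyte, -0.57 for erythroid and -1.45 for mesothelial cells. Leaving out 1 library moved 8 of the 12 lists by sex and 11 of the 17 by E2 over 1.5 times, with the values beside the results.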

How the results depend on the processing

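Leaving out the 4 libraries with a high Saa1, the block in a fit of only the groups compared, the averaged contrasts and list means without each library were chosen after seeing the data. Where nothing else is said, the cause was not tested. TMM factors moved 0 of 14 counts by over 1.5 times, and the median over all genes stayed between -0.019 and 0.033 in the 12 comparisons under every scaling. Alternatives were run on the 283 called values of genes picked by the naming rule, of which 78 were called in every alternative and 0 reversed, and on uncalled values of Ldlr. Of 135 list calls, 6 held with an estimated correlation, 114 with quantile normalization and 113 without the high Saa1 libraries, and at least 131 with each other setting. Leaving out 1 library moved the mean of 71 of the 135 lists by over 1.5 times and turned the sign of 5. Depth limits genes of few reads, since 3 reads were taken as the floor.

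Leaving out 1 library in turn changed the count for KO against WT from 2 to between 2 and 4 in intact females, from 95 to between 2 and 51 in males, from 1 to between 1 and 4 in placebo females and from 3 to between 1 and 10 in E2 females. For E2 the ranges were 246 to 1014 in WT (993 with all) and 1 to 29 in KO (1 with all), and for sex 355 to 1179 in WT (866) and 1069 to 1512 in KO (1965). Ovariectomy gave 9 to 210 in WT (108) and 1 to 57 in KO (16), genotype by sex 1 to 12 (1) and genotype by E2 1 to 35 (9). Averaged KO gave 3 to 16 (12) and averaged E2 195 to 827 (544).

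DESeq2 counted, for KO against WT, 28 genes in intact females, 462 in males, 57 in placebo and 61 in E2 females. It counted 1522 for E2 in WT and 85 in KO, 489 for ovariectomy in WT and 315 in KO, 30 for genotype by sex, 84 for genotype by E2, 92 for averaged KO and 1026 for averaged E2. The counts of edgeR were 25 for E2 in KO, 33 for ovariectomy in KO, 0 for genotype by sex and 22 for genotype by E2. Here and below, counts that stayed within 1.5 times are left out.

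With a mean of 50 or more, and so fewer genes tested, KO against WT gave 1 in intact females and 144 in males, E2 in KO 0, ovariectomy 213 in WT and 4 in KO, and each interaction 0. With no filter, KO against WT gave 4 in intact females, 46 in males, 3 in placebo and 8 in E2 females, E2 gave 613 in WT and 3 in KO, ovariectomy 12 in WT and 9 in KO, and each interaction 2. With no trend, KO against WT gave 32 in males and 2 in placebo females, E2 in KO 10, ovariectomy 17 in WT and 10 in KO, and averaged KO 4. A fit of only the groups compared, with fewer libraries to estimate the spread, gave 1 in intact females, 5 in males and 0 in E2 females for KO against WT. It gave 52 for E2 in WT and 0 in KO, 285 for sex in WT, 2 for ovariectomy in WT and 2 in KO, 4 for genotype by sex, 0 for genotype by E2 and 225 for averaged E2.

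A pseudocount of 0.5 gave 8 for ovariectomy in KO, and a pseudocount of 5 gave 2 for KO in placebo females, 19 for E2 in KO and 21 for genotype by E2. Quantile normalization gave 54 for KO in males, 63 for ovariectomy in WT and 6 in KO, and 1 for genotype by E2. Leaving out the high Saa1 libraries leaves 1 KO male, assumed to vary like the other groups, and 2 E2 females of each genotype, so lost calls there are no measure of Saa1. KO against WT then gave 1 in males and 1 in E2 females, E2 gave 249 in WT and 23 in KO, sex in KO 536, ovariectomy in KO 1, each interaction 0 and averaged KO 3.

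The replicate block gave 49 for KO in males, 3 for E2 in KO, 22 for ovariectomy in WT and 6 in KO, and 6 for averaged KO. The replicate block in a fit of only the groups compared gave 1 for KO in intact females, 2 in males and 0 in E2 females, 20 for E2 in WT and 0 in KO, 220 for sex in WT, and 0 for ovariectomy in WT and 1 in KO. For KO against WT in placebo and in E2 females, the block changed no other call than those named beside the results.

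Values of Ldlr that were not called turned in direction in 4 comparisons. For KO in placebo females they ran from -0.137 without WT placebo female 1 to 0.287 without WT placebo female 3, and for KO in E2 females from -0.187 to 0.076, the latter without KO E2 female 1. In E2 females the value was also 0.016 without WT E2 female 2 and 0.007 without the high Saa1 libraries. For ovariectomy in WT they ran from -0.373 without WT placebo female 3 to 0.051 without WT placebo female 1, and for genotype by E2 from -0.347 to 0.077 on leaving out the same 2 libraries.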

Other observations

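For 4 Y-linked genes every KO male lay below every WT male. The spread used includes females near 0, so that 0 passed decides nothing. Ddx3y was at 2117 ± 207 and 2968 ± 75.3 (-0.49, adjusted p = 0.597), Eif2s3y at 1066 ± 40.6 and 1855 ± 252 (-0.79, 0.309), Uty at 717 ± 98.1 and 1008 ± 53.3 (-0.50, 0.747), and Kdm5d at 716 ± 52.6 and 914 ± 54.1 (-0.35, 0.732).

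Saa1 was above 5000 in WT E2 female 2 (147442.3), KO E2 female 3 (36426.3), KO male 3 (29394.1) and KO male 1 (8371.5). In WT E2 female 2, Alb took 4.34% of reads. The chi-square per gene was 201 and 196 between this library and the other WT E2 females, and 48.7 between those. The ribosomal RNA model CT010467.1, among the 95 changed genes of KO against WT males, was at 9946 ± 1432 and 4316 ± 196 (1.20, adjusted p = 0.0494), and ran from 3555.6 to 12670.5 in WT intact females. These features were chosen after their values were seen.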
